A study of Mus musculus with 8 samples.

How the data were processed

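Total RNA from the subventricular zone of the lateral ventricle, microdissected from 7-month-old female mice, was measured on 2-colour expression arrays with Agilent probe identifiers. There were 8 samples, 4 from 3xTg mice and 4 from wild-type (WT) mice of the control strain, and per the labels' design text the replicates are biological. Per the labels, each 3xTg sample shared 1 array with the WT sample of the same replicate number, so the 8 samples lie on 4 arrays. Every 3xTg sample is labelled Cy5 and every WT sample Cy3 in the labels, with no dye swap. The labelling protocol names only Cy3-labelled nonamers, so Cy5 for the 3xTg samples rests on the label field alone. By that field genotype and dye are the same contrast on every array. A dye effect specific to a probe then cannot be separated from genotype in any fit.

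The deposited table holds 1 log2 intensity per probe and sample, already normalized by the authors, for 32684 probes and with no missing value. Per the submitters' processing notes limma was used, with no version given. The background correction, the normalization method and any probe filter are not given in the sources used here. The scanner files were not used here, so detection above background could not be assessed and a low intensity is not a statement that a gene was silent. Sample medians lay between 10.12 and 10.15 log2 units. In each sample between 109 and 288 probes were tied at the highest value, which lay between 15.98 and 16.00 and near the limit of a 16-bit scanner; 136 probes were at this value in every 3xTg sample and 99 in every WT sample, and none of these passed the test below. Precision is limited by the number of arrays, which is 4.

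Probes were named through the platform annotation supplied with the data, giving 1 gene symbol for 29769 probes, several for 0 and none for 2915, which are unnamed here. Of the named probes, 29519 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6 and 250 were not, and 0 symbols changed. That table was used only for names and chromosomes and for the order of neighbouring genes. The probes covered 21363 genes.

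The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a fixed effect for each array and 1 for genotype (3xTg minus WT), default empirical Bayes moderation, and Benjamini-Hochberg adjustment over all 32684 probes at a threshold of 0.05. The p-values of limma are two-sided. The shared array was checked: over all probes, deviations from the group means correlated between the samples of replicates 1 to 4 at r = 0.78, 0.78, 0.54 and 0.82, against at most 0.18 for samples of different arrays. Differences are given as log2 3xTg minus WT with their standard error (SE), over 4 arrays.

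Gene lists were tested with camera in limma at its preset inter-gene correlation of 0.01, with 1 probe per gene (the brightest on average), adjusted over the 37 lists with at least 5 measured genes. At the preset correlation camera sets a list against the other genes, so its p does not measure the spread between mice. Each list was also tested with an estimated correlation and with fry. For each list the number of members that passed is given over all probes and adjusted over the list alone. The lists, the fit, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined, with 1 exception, a fit without replicates 1 and 2 together, which was added after seeing the data. That rule names the transgene loci, the 10 probes of largest increase and the 10 of largest decrease that passed and had 1 sign on all 4 arrays, up to 3 members of smallest p in each list, Scd1, Scd2 and Fasn, and Xist and Y-linked genes as a check of sex. A further gene in that rule, and a test chosen later that needs it, are not reported here. Genes outside the rule are given as examples of a list and were chosen after their values were seen. Where a gene had several probes, the probe named by the rule is reported, and the text says so where the difference of another probe had the opposite sign.

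The alternatives were a fit without the array, the array as a random block (with statmod 1.5.0), centring on sample medians, quantile normalisation, loess within arrays at a span of 0.3, moderation with a trend and robust settings, leaving out the dimmest 25% of probes, leaving out each array in turn, using only probes with 1 symbol, averaging all probes of a gene, and other forms of the list test. The fit was tested on simulated data with the probe means of these samples and 200 changed probes among 32684. Probe variances were drawn from the distribution that limma fitted, and the noise was normal and independent between probes, with no dye effect. It recovered 4.55% of probes changed by 0.5 log2 units, 83.6% of those changed by 1 and 98.5% of those changed by 2, and 6 of its 131 calls were false. Small changes are therefore mostly missed at this number of arrays. The simulated data follow the fitted model, so their share of false calls does not measure that of the real arrays.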

Results

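Transcript levels in the neurogenic niche of the lateral ventricle were compared between 3xTg mice and wild-type (WT) controls. The 3xTg line is a model of Alzheimer's disease whose alterations include human APP and MAPT transgenes, driven by a Thy1 cassette. The subventricular zone holds neural stem cells, their proliferating progeny, neuroblasts and ependymal cells, and lies against the striatum and near the septum. Samples came from 4 3xTg and 4 WT female mice aged 7 months, hybridised as 4 pairs on 4 arrays, with 3xTg in Cy5 and WT in Cy3 on each. The correlation of all probes was 0.984 to 0.986 between the samples of an array and 0.920 at the lowest between any 2 samples. Each difference is 3xTg minus WT in log2 units of normalized intensity over 4 arrays, and it holds genotype and dye together.

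The transgene loci of 3xTg were examined first. App (A_55_P2012201) measured 14.48 ± 0.13 in 3xTg and 14.30 ± 0.07 in WT (SD, n = 4 each), a difference of 0.18 ± 0.10 (SE) that was positive on all 4 arrays and did not pass (limma, adjusted p = 0.405). The 3 probes for Mapt, which encodes tau, differed by -0.11, 0.08 and 0.11 (adjusted p = 0.719, 0.744 and 0.56). Thy1 differed by -0.06 ± 0.18 (adjusted p = 0.895). These probes were designed for mouse transcripts and how well they bind the human transgene transcripts is not known, so they do not check the genotype labels. The Y-linked gene Eif2s3y was at 9.18 in 3xTg and 9.03 in WT, and the brighter Xist probe at 14.71 and 14.75, in samples all labelled female. The other Xist probe differed by -0.48 (adjusted p = 0.0971).

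Across the array, 203 probes were higher and 197 lower in 3xTg (limma, adjusted over all probes), corresponding to 170 and 169 named genes. The largest increases were in Prune2, Kmt2d, which encodes a histone H3 lysine 4 methyltransferase, Irs4, an insulin receptor substrate, Xaf1, an interferon-inducible regulator of apoptosis, Fn3krp and Trim30d. The largest decreases were in Ldb3, Pop4, a subunit of ribonuclease P, Pttg1 and the transcription factor Pou6f1. Pttg1 is securin, which keeps sister chromatids from separating before anaphase. Further large decreases were in the phospholipase Pla2g4e, Hjurp, the chaperone of the centromeric histone Cenpa, the RNA demethylase Alkbh5 and the complement protease Masp2. Prune2 (A_55_P2067316) measured 12.59 ± 0.22 in 3xTg against 8.97 ± 0.22 in WT (SD, n = 4 each), a 12.3-fold difference (log2 3.62 ± 0.12 SE, adjusted p = 0.000109 by limma). Kmt2d was 7.92-fold higher (log2 2.98 ± 0.12 SE, adjusted p = 0.000181). Differences were 1.96 for Irs4, 1.87 for Xaf1, 1.83 for Fn3krp and 1.81 for Trim30d, with adjusted p of 0.0409, 0.0194, 0.0022 and 0.034. Differences were -2.38 for Ldb3, -2.34 for Pop4, -2.34 for Pttg1 and -2.28 for Pou6f1, each with an SE between 0.12 and 0.14 and adjusted p of 0.000967, 0.000967, 0.000639 and 0.00108. Next came Pla2g4e (-2.15), Hjurp (-1.98), Alkbh5 (-1.97) and Masp2 (-1.91), with adjusted p of 0.000967, 0.000461, 0.000958 and 0.0165. The predicted transcripts Gm5796, Gm3264 and Gm3002, which belong to a repeated gene family on chromosome 14 that single probes might not tell apart, were higher by 1.89, 1.78 and 1.76, while Gm3219 (-2.43) and A730008H23Rik (-2.07) were lower.

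**Figure D1:**
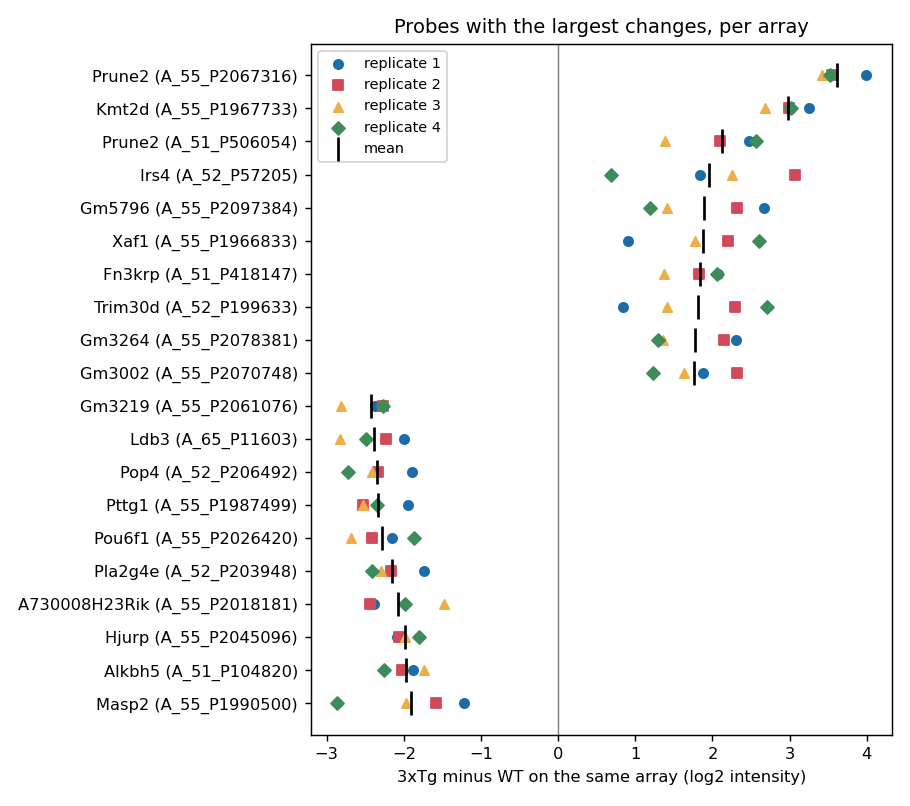
Difference between the 3xTg and WT samples of each array (log2 intensity, x axis) for the 20 probes of largest change that passed the test, 10 higher and 10 lower in 3xTg. Symbols mark replicates 1 to 4 and the black bar their mean; every symbol of a probe lies on the same side of 0, and the means run from 3.62 for Prune2 to -2.43 for Gm3219.

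Probes of a gene did not always move together. A second Prune2 probe (A_51_P506054) was higher by 2.13 (adjusted p = 0.00448) and the other two differed by -0.13 and 0.12. Kmt2d differed by 0.87 and 0.43 at its other probes, Irs4 by 0.49, Alkbh5 by -0.65 and -0.28, Xaf1 by -0.22, Ldb3 by -0.38, and Masp2 by -0.32 and -0.29. Hjurp was lower at all 3 probes (-1.98, -1.81 and -1.45), as was Pttg1 at its second probe (-0.88, adjusted p = 0.0325). Genes that passed lay near one another more often than by chance: 133 of 332 with a known neighbour order had another within 5 measured genes, against a mean of 48.3 in permutations (permutation p = 0.001, the smallest they can give). Prune2, Pop4, Masp2, Trim30d and Pla2g4e are among these 133, as are Elovl7, Abcg1, Cenpa, Zic1, Per3 and Rpl13a, which are described in the following paragraphs.

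Of all probes 25.4% had 1 sign on the 4 arrays, where chance gives 12.5% for independent arrays, and 5888 had an unadjusted p under 0.05, where chance gives 1634. The number of calls rested on the pairing and on single arrays. Without the array in the fit 47 probes were higher and 31 lower. With 1 array left out, 74 probes were higher and 57 lower without replicate 1, 12 and 19 without replicate 2, 185 and 229 without replicate 3, and 151 and 127 without replicate 4. Of the 20 probes of largest change, 12 passed without replicate 2, and that fit gave 2777 probes at an unadjusted p under 0.05. In the fixed gene lists each gene stands for its brightest probe, and counts of members that passed refer to that probe. At it 18 members passed over all probes (limma), and a further 10 genes passed only at 11 other probes, 4 of them with the opposite sign at the brightest. Without replicate 2, 0 of the 18 and 0 of the 11 passed, which covers every such call named in the following paragraphs.

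Lipid metabolism in this niche was a question of the study, and 1 gene of fatty acid synthesis and desaturation passed over all probes. This gene, Elovl7, encodes a fatty acid elongase and rose by 0.67 ± 0.12 (SE; 1.6-fold, limma adjusted p = 0.0447). Scd1, the desaturase that makes oleate and other monounsaturated fatty acids, measured 13.36 ± 0.12 in 3xTg and 12.80 ± 0.14 in WT (SD, n = 4 each). Its difference of 0.56 ± 0.10 (SE; 1.47-fold, higher on 4 of 4 arrays) had an adjusted p of 0.0502 over all probes and 0.0093 adjusted over the list alone. Scd2 differed by 0.25 (adjusted p = 0.24) and Fasn, the fatty acid synthase, by -0.20 (adjusted p = 0.481). Of the 30 measured genes of fatty acid synthesis and desaturation, 21 lay above 0, 1 passed over all probes and 2 passed adjusted over the list alone. The list as a whole had a median of 0.05 and did not pass (camera, adjusted p = 0.306).

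Other lipid genes that passed were spread over lists that did not. Mgll, the monoacylglycerol lipase, fell by 0.83 ± 0.11 (SE, limma adjusted p = 0.0198), Fabp5, a fatty acid binding protein, fell by 0.67 ± 0.11 (adjusted p = 0.0358), and the sterol exporter Abcg1 rose by 0.53 ± 0.09 (adjusted p = 0.0452). Medians were 0.0025 over 32 genes of triglycerides and lipid droplets, 0.02 over 33 of fatty acid uptake and oxidation, 0.06 over 20 of cholesterol synthesis and 0.09 over 14 of sterol transport and apolipoproteins, with adjusted p of 0.785, 0.991, 0.646 and 0.386 (camera). For the first 3 of these the mean of the list had the opposite sign to its median. In cholesterol synthesis 4 genes passed adjusted over the list alone and 0 over all probes, among them Lss (-0.54), Fdps (-0.53) and Hsd17b7 (-0.39, with 0.08 and 0.17 at its other probes). Npc1, which moves cholesterol out of lysosomes, differed by 0.55 (adjusted p = 0.0826). Apoe differed by -0.27 (adjusted p = 0.312).

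Proliferation genes fell as a group. Of 43 measured genes 31 lay below 0, the median was -0.18, and the list passed (camera, adjusted p = 1.35e-05), with an adjusted p of 0.743 with an estimated correlation. Cenpa, the histone variant of centromeres, fell by 1.16 ± 0.16 (SE, limma adjusted p = 0.0215), and the chromatin protein Hmgb2 fell from 13.34 ± 0.24 in WT to 12.34 ± 0.55 in 3xTg (SD, n = 4 each; adjusted p = 0.0225). The replication helicase subunit Mcm7 (-0.63 ± 0.10) and Ube2c (-0.71 ± 0.11), a ubiquitin-conjugating enzyme of mitosis, also fell (adjusted p = 0.0341 and 0.0346). Ccnd1, cyclin D1, went the other way and rose by 1.36 ± 0.14 (2.57-fold, adjusted p = 0.00757). Adjusted over the list alone, 14 genes passed as lower, with Ccnd2 (-0.96), Kif11 (-0.80) and Mcm6 (-0.53) among them, and 2 as higher. The medians on the arrays of replicates 1 to 4 were -0.21, -0.32, -0.21 and -0.14, and the median was -0.27 without replicate 4. Hjurp and Pttg1, which act in mitosis and were named above, are not members of this list.

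Of the lists for the other cell types of the niche, only that of oligodendrocytes and myelin passed. Medians were -0.02 for 35 genes of transit-amplifying cells and neuroblasts, 0.0014 for 34 of astrocytes and neural stem cells, 0.0019 for 41 of ependymal cells and motile cilia, and 0.01 for 17 of oligodendrocyte precursors (camera, adjusted p = 0.678, 0.991, 0.669 and 0.991). Adjusted over the list alone, 3 neuroblast genes passed as higher and 3 as lower, with Sp9 at 0.79 and Sox11 at -0.54, and 0 passed over all probes. Id2 differed by -0.63 and Gfap by 0.31 (limma adjusted p = 0.062 and 0.167). Oligodendrocyte and myelin genes were higher, with 28 of 33 above 0 and a median of 0.21 (camera, adjusted p = 0.00358, and adjusted p = 0.763 with an estimated correlation). Ugt8a, which makes galactosylceramide, differed by 0.69, Gpr37 by 0.60, Gjc3 by 0.53 and Ppp1r14a by -0.55; these 4 passed adjusted over the list alone, and 0 passed over all probes. The myelin medians per array were -0.17, 0.44, 0.50 and 0.17, and without replicate 3 the median was 0.11 and the list did not pass (adjusted p = 0.316); it was 0.37 without replicate 1.

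Interferon-response genes were higher in 3xTg. Of 40 measured genes 39 lay above 0, with a median of 0.32 (camera, adjusted p = 1.90e-08, and adjusted p = 0.743 with an estimated correlation). Xaf1 rose by 1.87 ± 0.24 (SE, 3.66-fold, limma adjusted p = 0.0194) and Eif2ak2, the double-stranded RNA sensor PKR, by 1.32 ± 0.17 (2.49-fold, adjusted p = 0.0208). Ifit3 differed by 1.78 ± 0.36, Ifit1 by 1.79 ± 0.42 and Oasl2 by 1.77 ± 0.40, each higher on 4 of 4 arrays with adjusted p of 0.0697, 0.096 and 0.0903. Adjusted over the list alone 7 genes passed, all higher. The median was above 0 on each array, at 0.10, 0.27, 0.20 and 0.73 for replicates 1 to 4, and it was 0.20 without replicate 4. Trim30d, Trim34a and Trim12a, neighbouring genes on chromosome 7 of a family with interferon-inducible members, were higher by 1.81, 1.19 and 1.54, although a second Trim34a probe differed by only 0.0027; the last 2 were chosen after their values were seen.

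Genes of complement and antigen presentation were also higher as a list, with 19 of 24 above 0 and a median of 0.14 (camera, adjusted p = 0.0326, and adjusted p = 0.743 with an estimated correlation). The largest differences were in class I genes, with B2m at 0.97 ± 0.18 (SE, limma adjusted p = 0.0521), H2-T23 at 0.79 ± 0.20 and H2-D1 at 0.72 ± 0.16; these 3 passed adjusted over the list alone, and 0 passed over all probes. The medians of this list on the arrays of replicates 1 to 4 were -0.04, 0.15, 0.18 and 0.34. The list did not pass without replicate 3 (median 0.13, adjusted p = 0.0564) or without replicate 4 (median 0.11, adjusted p = 0.188). Microglial markers had a median of -0.02 over 33 genes (adjusted p = 0.386), with Ly86 at -0.64 and Tmem119 at -0.46. Disease-associated microglial genes had a median of -0.03 over 24 genes and reactive astrocyte genes 0.10 over 30, and neither list passed (adjusted p = 0.991 and 0.177).

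Markers of striatal projection neurons were lower in 3xTg as a list, while 0 of its 29 genes passed singly at the brightest probe (limma, over all probes or adjusted over the list alone). In all, 28 lay below 0 and the median was -0.82 (camera, adjusted p = 1.90e-08, and adjusted p = 0.743 with an estimated correlation). Gpr6 differed by -0.82 ± 0.21, Drd3 by -0.75 ± 0.20 and Gng7 by -0.95 ± 0.27 (SE, adjusted p = 0.119, 0.12 and 0.137), and Arpp21 passed at another probe (-1.25, adjusted p = 0.0291, with -1.26 at the brightest). Arrays differed in this list: the medians were -1.59 and -1.43 in replicates 1 and 2, and 0.21 and -0.29 in replicates 3 and 4. With replicates 1 and 2 left out the median was 0.04 and the list did not pass (adjusted p = 0.582); it was -0.52 without replicate 1 alone. Synaptic and general neuronal genes had a median of -0.04 over 27 genes (adjusted p = 0.408).

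Septal and cholinergic markers went the other way, with 9 of 13 above 0 and a median of 0.68 (camera, adjusted p = 0.0297, and adjusted p = 0.763 with an estimated correlation). The transcription factors Zic1 and Isl1 rose by 1.49 ± 0.27 and 0.71 ± 0.12 (SE, limma adjusted p = 0.0496 and 0.0429), and 6 genes passed adjusted over the list alone, Zic2 (1.55) among them. The medians per array were 0.87, 0.81, 0.12 and -0.17, and the list did not pass without replicate 1 (median 0.31, adjusted p = 0.276) or without replicates 1 and 2 (median 0.06, adjusted p = 0.55). Cortical and hippocampal glutamatergic markers were lower, with 18 of 23 below 0 and a median of -0.42 (adjusted p = 0.0014, and adjusted p = 0.743 with an estimated correlation); 0 passed singly at the brightest probe, where Mef2c (-0.57), Nrgn (-0.41, saturated in 2 samples) and Kcnv1 (-0.76) had the smallest p, and Camk2a passed at another probe (-0.68, adjusted p = 0.0403, with 0.02 at the brightest). Their medians per array were -0.43, -0.77, -0.69 and 0.25. Immediate early genes, which neuronal activity induces, were lower with 20 of 27 below 0 and a median of -0.25 (adjusted p = 0.00433, and adjusted p = 0.743 with an estimated correlation). Gadd45b fell by 0.76 ± 0.12 (adjusted p = 0.0377), and 6 genes passed adjusted over the list alone, with Homer1 (-0.86) and Ier5 (-0.44) among them. At other probes Homer1 differed by -0.84 (adjusted p = 0.0473), -0.45, -0.43 and -0.02, and Ier5 by 0.23. The immediate early list had medians of -0.53, -0.27, -0.08 and 0.13 on the 4 arrays and did not pass without replicate 1 (median -0.15, adjusted p = 0.353); the median was -0.38 without replicate 4 and 0.03 without replicates 1 and 2.

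**Figure D2:**
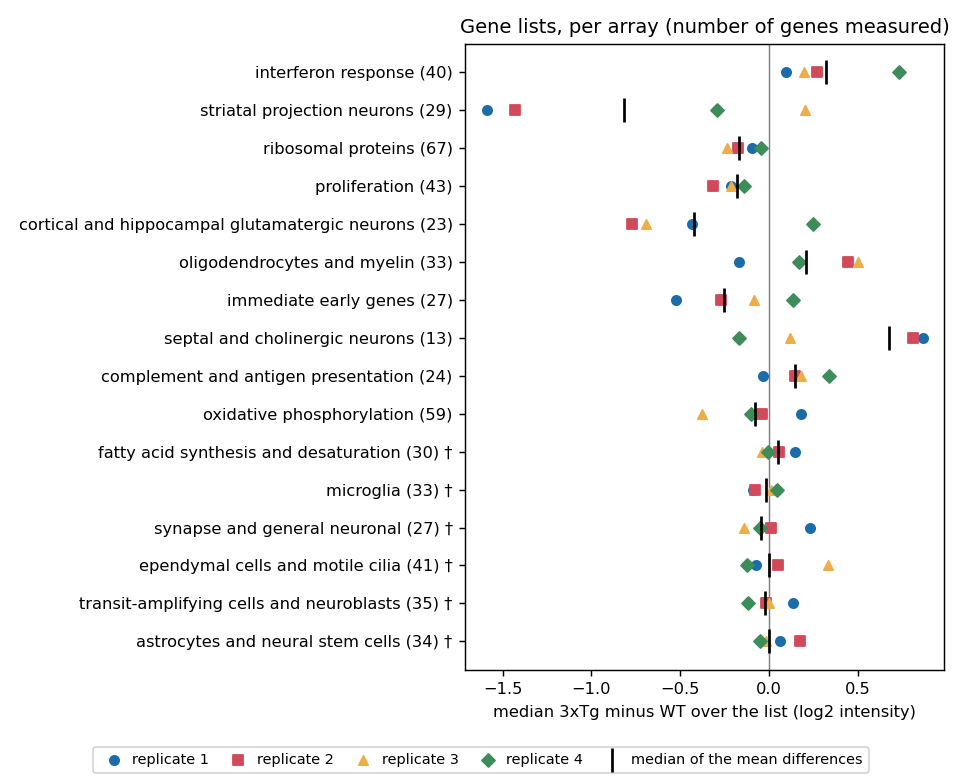
Median difference between the 3xTg and WT samples of each array (log2 intensity, x axis) over the genes of 16 lists, with the number of genes measured in parentheses and a dagger at lists that did not pass camera at the preset correlation. Symbols mark replicates 1 to 4 and the black bar the median over genes of the mean difference; striatal medians run from -1.59 in replicate 1 to 0.21 in replicate 3, and interferon-response medians from 0.10 to 0.73.

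Ribosomal protein genes were lower by a small amount, with 52 of 67 below 0 and a median of -0.17 (camera, adjusted p = 1.57e-06, and adjusted p = 0.743 with an estimated correlation). Rpl13a fell by 0.62 ± 0.11 at its brightest probe (SE, limma adjusted p = 0.0444), with -0.18 and -0.09 at its other probes, and 5 genes passed adjusted over the list alone. Rpl29 differed by -0.83 at its brightest probe (adjusted p = 0.0542) and passed at its other (-0.77, adjusted p = 0.0342). Probes disagreed for Rpl15, at -0.42 for the brightest (adjusted p = 0.0986) and 0.71 for the other (adjusted p = 0.0221), and Rps3a1 was higher at 2 probes (0.87 and 0.59, adjusted p = 0.00909 and 0.042), with 0.08 at its brightest. Oxidative phosphorylation genes had a median of -0.08, with 39 of 59 below 0 (adjusted p = 0.0326, and adjusted p = 0.875 with an estimated correlation), and 0 passed singly. Cox6a1 differed by -0.50 ± 0.10, with 2 saturated samples. The oxidative phosphorylation medians on the arrays of replicates 1 to 4 were 0.18, -0.04, -0.37 and -0.10. The oxidative phosphorylation list did not pass without replicate 3 (median -0.0025, adjusted p = 0.969) or without replicate 4 (median -0.10, adjusted p = 0.0539), and its median was -0.15 without replicate 1.

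The circadian clock list did not pass (median -0.09, adjusted p = 0.179), yet Per3 rose by 1.05 ± 0.16 (SE, limma adjusted p = 0.0301) and Nr1d1 fell by 0.73 ± 0.13 (adjusted p = 0.0474). Per1 (-0.77) and Nr1d2 (0.61) passed at a probe other than the brightest (adjusted p = 0.0213 and 0.0409), with 0.25 and -0.15 at the brightest. Genes of amyloid and tau processing had a median of -0.09 over 27 genes (camera, adjusted p = 0.162); Apbb1, which binds the intracellular tail of App, fell by 0.58 ± 0.10 (limma adjusted p = 0.0409). The Notch, Wnt, Hedgehog and BMP and TGF-beta lists had medians of -0.0037, -0.05, 0.09 and 0.01, and growth factor and insulin signalling -0.03, with adjusted p from 0.306 to 0.991. Fzd2 (-0.93) and Bmp4 (0.58) of these lists passed at another probe (adjusted p = 0.0136 and 0.0436), with -0.01 and 0.11 at the brightest. In the Hedgehog list Boc, a co-receptor, differed by 0.51 (adjusted p = 0.0826) and Shh by 0.91 (adjusted p = 0.148). Medians were 0.11 for choroid plexus epithelium, -0.09 for endothelial cells and pericytes, 0.0037 for meninges and fibroblasts and 0.14 for blood cells (adjusted p = 0.306, 0.195, 0.991 and 0.162). Those of glucocorticoid and stress response, heat shock and unfolded protein response, and lysosome and autophagy were -0.04, 0.0012 and 0.01 (adjusted p = 0.195, 0.93 and 0.615). In several lists that did not pass, the median lay above 0 and the mean below it (astrocytes and neural stem cells, lysosome and autophagy, heat shock, meninges, BMP and TGF-beta), or the reverse (disease-associated microglia). In all, 10 of 37 lists passed at the preset correlation, 4 higher and 6 lower. Other assignments of genotype within the arrays passed 4 to 13 lists, so this number does not set the real assignment apart. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. In fry 0 passed as a shift to 1 side (lowest adjusted p = 0.0724), while 20 passed as changed in either direction.

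**Figure D3:**
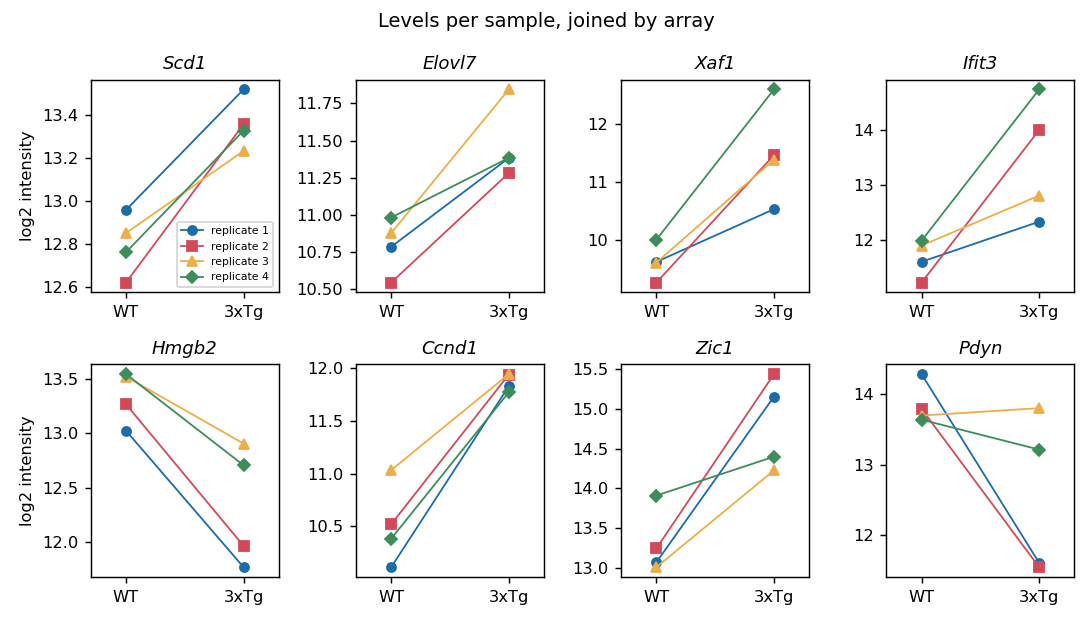
Normalized log2 intensity (y axis, a separate scale for each gene that does not start at 0) of 8 genes in the WT and 3xTg sample of each array, joined by a line per replicate. Scd1, Elovl7, Xaf1, Ifit3, Ccnd1 and Zic1 were higher in 3xTg on 4 of 4 arrays and Hmgb2 lower, while Pdyn, a striatal marker chosen after its values were seen, differed by -2.67 and -2.24 in replicates 1 and 2 and by 0.11 and -0.42 in replicates 3 and 4. At a second Pdyn probe, not drawn, replicates 1 to 4 differed by -1.67, -2.09, -0.52 and -0.48.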

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

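The tests of the 3 patterns described here were chosen only after those results were seen; the counts over other splits of the samples were planned.

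Genotype can be assigned within the 4 arrays in 8 ways, too few for a share under 0.05. The real assignment was the only 1 of the 8 with as many probes higher (203, highest other 0), lower (197, highest other 0) or at an unadjusted p under 0.05 (5888, highest other 3009), while 3 of the 8 gave as many gene lists (10, highest other 13). In the fit without the array, chance could not be excluded over the 35 splits of the 8 samples. A split and its mirror swap higher and lower, so the larger direction of each other split was compared. There 3 of the 35 splits, the real one included, gave as many probes in 1 direction as the real one gave higher (47, highest other 1916). Counted the same way, 3 gave as many as it gave lower (31, highest other 1916, the same split). Again with the real one included, 10 gave as many at an unadjusted p under 0.05 (2071, highest other 8259) and 4 as many lists (10, highest other 17). The 2 other splits with calls kept both samples of every array together and called 461 and 2446 probes. These 2 point to the arrays, or the pairs of mice on them, as a structure of the samples. A further split that kept every array together called 0 probes, with 1034 at an unadjusted p under 0.05.

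Genes that passed lay close together in the genome, with both directions mixed: among named genes of different families, 113 of 297 had another such gene within 5 measured genes, against a mean of 44.2 and a maximum of 71 in 1000 permutations. A dye effect that hits single probes regardless of genome position gives no reason for neighbours to pass together. The permutations matched genes only on their number of probes. They cannot exclude a dye effect that neighbouring genes share, since each genotype had 1 dye on every array. A sequence variant under the probe that passed is argued against as the cause for all of these genes. Of 180 genes with further probes, the others moved in the same direction on average in 141, and over the 180 by a median of 0.27, against at most 0.06 in 200 draws of random genes. That is less than the median of 0.87 at the called probes, and such a variant stays open for the 39 other genes, for part of the change in the 141 and for the 159 genes with 1 probe. Called pairs 6 to 20 genes apart were also in excess (127, mean of permutations 74.2). So were pairs 21 to 50 genes apart (217, mean of permutations 144.3), so the excess was not confined to close neighbours. Linked variants that differ between the mouse lines could give such an excess, although the labels name the same B6 and 129S background for both. An effect of genotype on other genes remains open.

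Striatal markers were lower in the 3xTg samples of replicates 1 and 2. All 3xTg samples carried the same dye, yet their centred striatal medians were -1.09 and -1.05 in replicates 1 and 2 and 0.26 and 0.46 in replicates 3 and 4. This gap of 1.31 exceeds the range of 0.53 among WT samples and argues against a dye effect of constant size as the cause of the drop in replicates 1 and 2, while a smaller one common to all arrays stays open. In replicates 1 to 4, 0, 1, 25 and 8 of 29 striatal genes lay above 0. Replicate 3 thus went against a genotype effect in every pair, with a median of 0.21. It was the only replicate with a median above 0, and 1 pair of mice does not exclude such an effect. The septal median was higher in replicates 1 and 2, the lower one there exceeding the higher one in replicates 3 and 4 by 0.69. A dissection with less striatum and more septum in those 2 samples is therefore a candidate explanation. The septal rise was not confined to them, however: 12, 9, 10 and 5 of 13 septal genes lay above 0 in replicates 1 to 4. Isl1 (0.87, 0.99, 0.43 and 0.56) and Zic1 (2.08, 2.19, 1.22 and 0.49), which passed, were higher on all 4 arrays. A biological difference between these mice was not tested and remains open.

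Interferon-response genes were higher in 3xTg on all 4 arrays. The list's medians spanned 0.64 over arrays. Centred medians in the 3xTg samples, all in 1 dye, were -0.16, 0.35, -0.07 and 0.66 in replicates 1 to 4. Those of the WT samples were -0.20, -0.07, -0.34 and -0.22. This argues against a dye effect of constant size as the sole cause of the higher levels in 3xTg replicates 2 and 4. Each genotype had 1 dye, so a dye effect common to all arrays cannot be told apart from genotype. More microglia in the 3xTg samples would raise microglial markers alike, but the median of the interferon list exceeded theirs by 0.34 (two-sided permutation p = 1e-04, the smallest possible). That permutation exchanged genes between the lists, so its p does not measure the spread between mice. Strain variants in a few of the list's own genes are argued against by 39 of 40 members lying above 0 in the mean difference. On the arrays of replicates 1 to 4, 27, 33, 31 and 37 did. A two-sided exact sign test on the 40 gave p = 7.46e-11. The list had already passed as higher and its members are not independent of one another, so this p is not separate support. A response that accompanies the 3xTg genotype remains open beside dye; differences between cages or in the health of single mice were not tested, and the list did not pass with an estimated correlation (adjusted p = 0.743).

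Single samples stood apart from the other 3 of their group in 9 of 268 groups of 4 examined, where chance gives about 13. Among 3xTg samples these were Prune2 (A_51_P506054) at 11.68 in replicate 4 (others 10.75 to 10.91), Gli1 at 11 in replicate 4 (others 11.59 to 11.61) and Neu4 at 11.63 in replicate 3 (others 11.22 to 11.23). Among WT samples they were Drd3 at 12.49 (others 12.08 to 12.10), Emp1 at 9.55 (others 9.12 to 9.18) and Cox6a1 at 15.8 (others 15.98 to 16.00, with 2 samples saturated) in replicate 1, and B2m at 12.14 in replicate 3 (others 11.99 to 12.01). In WT replicate 4, Gjc3 was at 12.67 (others 12.35 to 12.40) and Xist (A_52_P300376) at 14.58 (others 14.79 to 14.83).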

How the results depend on the processing

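The fit without replicates 1 and 2 together was the only alternative chosen after seeing the data; the cause of each change below was not tested, except that leaving out arrays leaves fewer samples. None of the 400 calls changed sign in the alternative fits that tested them, but most of these fits could not change one. All 400 calls had 1 sign on all 4 arrays, so leaving out arrays keeps the sign. Fits of the same values on all arrays give the same difference. Only median centring, quantile normalisation and loess could have changed a sign. Higher and lower counts were 47 and 31 with no replicate block (2071 at an unadjusted p under 0.05), 551 and 758 with the array as a random block, 132 and 115 after quantile normalisation, 405 and 500 with trend and robust moderation, and 101 and 60 without replicates 1 and 2 together (2248 at an unadjusted p under 0.05). Leaving out each replicate in turn gave 12 to 185 higher, 19 to 229 lower, 2777 to 6628 at an unadjusted p under 0.05 and 7 to 11 lists.

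With an estimated correlation 0 lists passed: interferon response (median 0.32), striatal neurons (-0.82), ribosomal proteins (-0.17), proliferation (-0.18), glutamatergic neurons (-0.42), myelin (0.21), immediate early genes (-0.25), septal neurons (0.68), complement and antigen presentation (0.14) and oxidative phosphorylation (-0.078). Over single replicates left out, these medians ranged from 0.20 to 0.38, -1.11 to -0.52, -0.18 to -0.13, -0.27 to -0.20, -0.62 to -0.29, 0.11 to 0.37, -0.38 to -0.15, 0.31 to 0.76, 0.11 to 0.21 and -0.15 to -0.0025 in the same order. Without replicates 1 and 2 together the striatal median turned to 0.040, the septal list (0.064) no longer passed, nor did the immediate early list (0.033, tested as lower). The septal list was also lost without the dimmest 25% of probes (0.43) and on ranks (0.68), and oxidative phosphorylation with the random block, with trend and robust moderation and without the dimmest probes (-0.078 each) and with all probes averaged (-0.045). Lists that passed newly were glucocorticoid and stress response without replicate 2 (-0.12) and with all probes averaged, reactive astrocytes without replicate 1 (0.14), choroid plexus without replicate 4 (0.21), and general neuronal genes (-0.16) and blood cells (0.15) without replicates 1 and 2 together. The no-block fit changed no list call. Over 134 named probes, 1543 of 1736 alternative values kept their side of the threshold (7 that never passed changed sign), 92 passed newly and 101 no longer passed. Scd1 passed with the array as a random block, after median centring or loess, with trend and robust moderation and without the dimmest probes (adjusted p over its alternatives 0.0084 to 0.691). Of the 18 list members that passed at their brightest probe, 9 did so after quantile normalisation, 1 (Ccnd1) with no replicate block, and 3, 0, 11 and 7 without replicates 1 to 4. Signal over background is unknown here and limits what dim probes show.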

Other observations

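The genes in this part were chosen after their values were seen. Outside the fixed lists, 2 subunits of the GABA-A receptor that neighbour each other were higher in 3xTg, Gabra2 by 0.97 ± 0.10 (SE, limma adjusted p = 0.00754, with 0.79 at its second probe) and Gabrg1 by 0.98 ± 0.15 (adjusted p = 0.0338). Glo1, the glyoxalase that clears methylglyoxal, rose by 1.13 ± 0.09 (adjusted p = 0.0031). Nptx2, a secreted pentraxin that gathers AMPA receptors at excitatory synapses, fell by 1.69 ± 0.21 (adjusted p = 0.0159) and was at -0.96 at its second probe (adjusted p = 0.045). Cx3cl1, the neuronal ligand of the microglial receptor Cx3cr1, fell by 0.78 ± 0.11 (adjusted p = 0.0221). The retroviral restriction gene Fv1, whose alleles differ between inbred mouse strains, fell by 1.52 ± 0.17 (adjusted p = 0.0106). Each of these had another gene that passed within 5 measured genes; without replicate 2, 31 of the 400 calls remained.

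Of 81 pairs of neighbouring genes that both passed, 36 moved in opposite directions. There were 53 runs of 2 or more such genes and 16 of 3 or more, the longest with 10 predicted or clone-named genes on chromosome 14. Striatal markers stood 0.77 below general neuronal genes in the difference between 3xTg and WT (list medians -0.82 and -0.04, permutation p = 1e-04, the smallest 10000 permutations can give). That permutation exchanged genes between the lists as if they were independent, so its p does not measure the spread between mice. With an estimated correlation the striatal list did not pass (camera, adjusted p = 0.743). The gap of 0.77 came mainly from replicates 1 and 2, where the striatal medians were -1.59 and -1.43 against 0.23 and 0.01. In replicate 4 they were -0.29 against -0.05, and in replicate 3 striatal markers lay above general neuronal genes, at 0.21 against -0.14.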
